A study of Mus musculus with 8 samples.

How the data were processed

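Microvessel fragments were isolated from 8 newborn mouse brains, 4 from wild-type controls and 4 from mice with the D849V knock-in allele of Pdgfrb, and their RNA was measured on 1-colour Affymetrix arrays, 1 array per brain. Per the labels' protocols, total RNA was column purified and 6 ug of it was turned into biotin-labelled cRNA. The deposited values are log2 expression values per probe set, made by the authors with GCRMA, per the submitters' processing notes; the version and options are not given in the sources used here. GCRMA estimates background from probe sequence, normalizes arrays by quantiles and summarises the probes of a probe set, so that dim probe sets collect at a common floor and their folds depend on it. That the scale is log2 was read from the values, which ran from 2.18 to 16.49 on the 8 arrays, with 19% to 22% of the probe sets of each array at the floor. No counts or depths belong to arrays; their number, 4 per group, limits the precision, and values near the floor are not resolved. A gene was taken to be at the floor in a group when all its arrays lay within 0.5 of the lowest value. Where all arrays of a group lay under the filter given next, as in 38 of the risen genes and 1 of the fallen, a fold is given as a lower bound, with that group set to the filter level of 4; fitted log2 differences of such genes depend on dim values.

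Of the 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 were unnamed here. No symbol of the platform annotation needed updating through the gene table of assembly GRCm38.p6, and older symbols of the gene lists were updated through it where it held them. That table was used only for names and for the order of genes along chromosome 18. The 18194 named genes, 9012 of them with several probe sets, were each represented by the probe set with the highest mean over the 8 arrays. Genes above a log2 value of 4 on fewer than 4 arrays were left out, 6748 genes in all, and 11446 (62.9%) were tested. Where a named gene passed and another of its bright probe sets differed in the other direction (3 genes), this is said. Some genes of the fixed lists had no probe set with a single symbol and were not analysed here.

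Groups were taken from the genotype in the labels. Litter, day of preparation and scan date are not given in the sources used here, so no batch could be tested. Each gene was tested between all mutant and all control arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test, the filter, 26 gene lists and the rule for named genes were fixed before the data were examined. That rule names Pdgfrb, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, and from each list up to 4 members with the smallest p among those that passed, or the 2 brightest where none did. Genes named outside it were chosen after their values were seen. Of the lists, 25 were tested with camera of limma with an inter-gene correlation of 0.01, and again with an estimated correlation and with fry; the sex-linked genes served as a check of the arrays. The mean of each list on each array, with genes centred, was compared by an exact two-sided permutation test over the 70 assignments of arrays to groups. Lists chosen after seeing the data are described as such.

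Alternatives were no filter, a stricter filter at 6, a second quantile normalization, centring of each array on its median, the replicate number as a block, the mean of the probe sets of a gene, preference for probe sets without a suffix for shared or variant transcripts, every probe set tested singly, the Y-linked genes as a covariate, array weights, eBayes with trend and robust settings, a threshold of 0.01, a fold of at least 2, and each array left out in turn. An alternative with only the 5 arrays that showed Y-linked transcripts was added after seeing the data. The fit was tested on simulated data for this comparison, over 11446 genes with 50 changed at each fold: 48% of the 1.5-fold changes, 72% of the 2-fold, 96% of the 4-fold and 100% of the 16-fold changes were recovered, with 8 false calls among 166. The simulated genes varied independently with normal noise, without a floor or shared array effects, so these rates need not hold for the real arrays.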

Results

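RNA abundance was measured on 8 single-colour oligonucleotide arrays, each hybridised with biotin-labelled cRNA made from 6 ug of total RNA from the microvessels of a separate newborn mouse brain. Fragments of small vessels, still carrying their pericytes, were pulled out of dissociated brains at postnatal day 1 with magnetic beads coated with an antibody against PECAM, a surface protein of endothelial cells. The 4 mutant brains carried a knock-in allele of Pdgfrb with the D849V substitution, which makes the PDGF receptor beta of pericytes signal without ligand. The 4 control brains were wild type, and the mice were on a mixed 129S/J background. The table held log2 GCRMA values for 45101 probe sets, from which 11446 genes were bright enough to test. Pearson correlations between arrays ran from 0.967 to 0.991 within the groups and from 0.932 to 0.968 between them, and no pair of arrays held identical values. The first principal component took 55.6% of the variance and had positive scores on the 4 mutant arrays and negative scores on the 4 control arrays.

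The comparison asks what an always-active PDGF receptor beta changes in the newborn brain microvasculature. Interferon-induced genes rose most in the mutant microvessels: Cxcl10, a chemokine that attracts activated T cells, was 560-fold higher and Ifit1, an antiviral RNA-binding protein, was at least 232-fold higher. Microglia and macrophage markers rose as well, with Ctss, a lysosomal protease, 4.78-fold higher. Several genes of the blood-brain barrier fell by smaller amounts, among them the cationic amino acid transporter Slc7a1, which fell by 0.59 on the log2 scale. Most markers of pericytes, smooth muscle cells and endothelial cells did not pass the test. In limma's test with Benjamini-Hochberg adjustment, 524 of the 11446 genes changed, 304 of them higher and 220 lower in the mutants, and 2363 genes had an unadjusted p under 0.05. The rises were the larger changes: the median of the risen genes was 1.84 and that of the fallen genes -0.60 on the log2 scale (1.82 and -0.60 with groups under the filter set to its level). Rises of at least 16-fold were fitted in 50 genes, 42 of them against that level too, while the largest fall was 4.41-fold. The 4 mutant and 4 control values did not overlap in 523 of the 524 changed genes and in 14.5% of all tested genes, against 2.86% by chance. The median difference over all tested genes was -0.11 on the log2 scale, and with each array centred on its median the split was 336 genes higher and 115 lower.

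**Figure D1:**
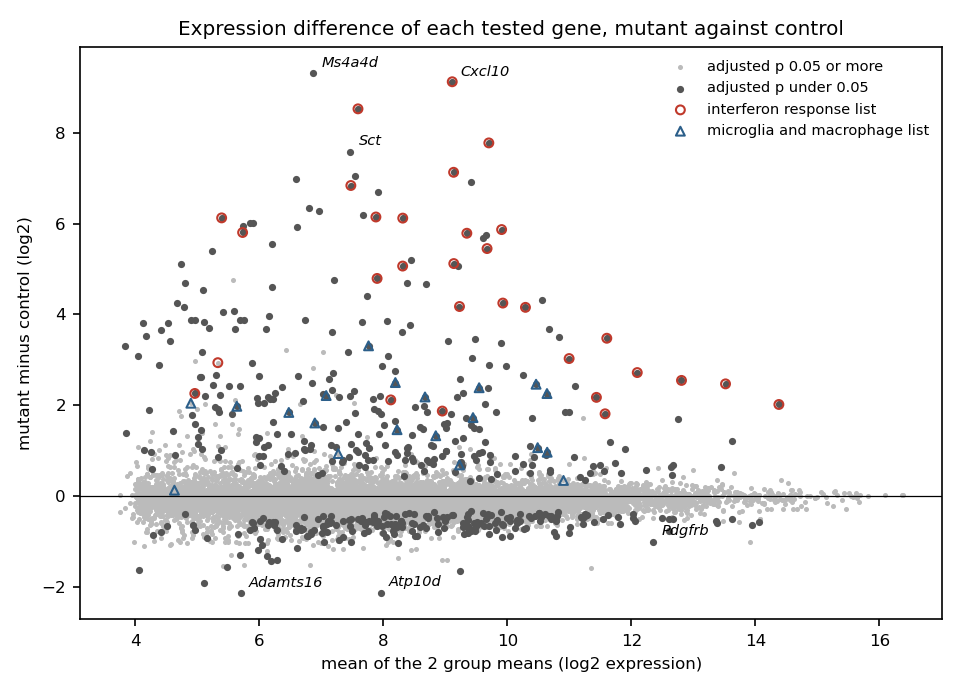
Difference between mutant and control (log2) of each tested gene against the mean of its group means (log2 expression), with dark points for genes with an adjusted p under 0.05, red rings for the interferon response list and blue triangles for the microglia and macrophage list. Rises reach 9.32 (Ms4a4d), whereas the deepest fall, of Adamts16, is -2.14, and the ringed genes all lie above 0.

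Pdgfrb itself, the gene that carries the substitution, gave different results on its probe sets. The brighter one fell by 1.01 on the log2 scale (SE 0.115, limma adjusted p = 0.00132), from 12.86 ± 0.05 in controls to 11.85 ± 0.21 in mutants (SD, n = 4 each). The dimmer one read 9.24 ± 0.41 in mutants and 9.15 ± 0.40 in controls (SD, n = 4 each), a difference of 0.09 (limma adjusted p = 0.887 over all probe sets). A single substitution need not alter transcript level, so these values do not check the labels of the arrays. Whether the knock-in allele alters the sequence that either probe set reads was not analysed here, so the lower signal of the brighter one need not be a lower transcript level. With the mean of its probe sets the difference was -0.46 (limma adjusted p = 0.144). Pdgfa, which encodes a PDGF chain, fell by 0.68 (SE 0.158, adjusted p = 0.0499). Of the 7 PDGF ligand and receptor genes tested, these 2 fell and none rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.279).

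The largest fitted difference, 9.32, was that of Ms4a4d, a membrane protein of the MS4A family, which read 11.53 ± 0.39 on the mutant arrays (SD, n = 4) and lay at the floor of the values on all 4 control arrays. Next in fitted size came Cxcl10 at 13.68 ± 0.24 against 4.55 ± 0.69, Ifit1 at 11.86 ± 0.19 against 3.33 ± 0.25 and Iigp1, an immunity-related GTPase, at 13.59 ± 0.17 against 5.81 ± 0.70 (mutant against control, SD, n = 4 each). Sct, the gene of the hormone secretin, rose by 7.59 on the log2 scale (SE 0.164, adjusted p = 4.47e-08). The other rises among the 10 largest were those of Ifit3 (7.13), the chemokine Cxcl11 (7.04), the nucleic acid sensor Zbp1 (6.98), Ifi27l2a (6.92) and Irf7 (6.84), a transcription factor that drives interferon genes, all with limma adjusted p of at most 1.39e-05. Where all control arrays lay under the filter, only a bound holds: at least 185-fold higher for Ms4a4d, 232-fold for Ifit1, 153-fold for Sct and 68-fold for Zbp1. The largest falls were those of the metalloprotease Adamts16 (-2.14, SE 0.296, adjusted p = 0.00429), the lipid flippase Atp10d (-2.13, adjusted p = 0.0163) and Hif3a, a hypoxia-inducible factor subunit (-1.91, adjusted p = 0.0133). Prxl2c (-1.66), the collagen chain Col14a1 (-1.64), the transcription factor Nfatc2 (-1.57), the secreted Wnt modulator Sfrp2 (-1.43), the long noncoding RNA Fendrr (-1.41), the receptor Tnfrsf25 (-1.33) and Sytl2 (-1.31) completed the 10 largest, with limma adjusted p up to 0.0487. Col14a1 lay under the filter on all mutant arrays and was at least 1.84-fold lower. A second, dimmer probe set of Prxl2c differed in the other direction, by 0.24.

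**Figure D2:**
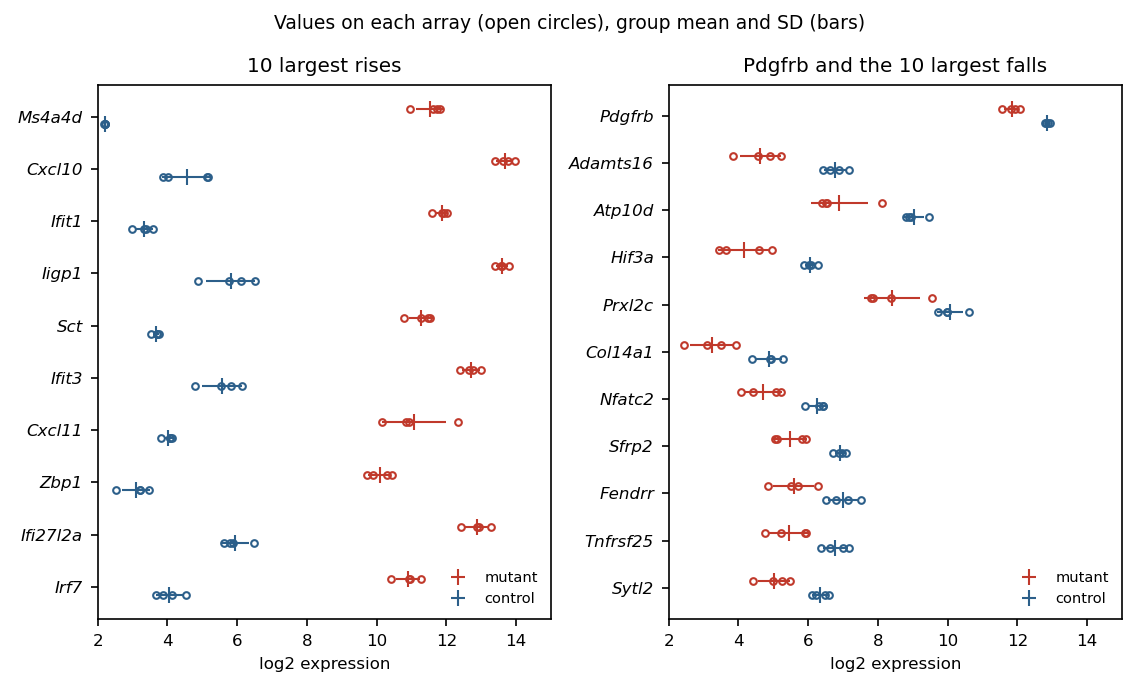
Log2 expression on each of the 8 arrays (open circles; mutant red, control blue) with the group mean (vertical tick) and SD (bar, n = 4), for the 10 largest rises on the left and for Pdgfrb and the 10 largest falls on the right. The groups do not overlap for any gene shown; Ms4a4d lies near 2.21 on the control arrays and Atp10d is higher on mutant array 3 (8.13) than on the other mutant arrays.

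Of the 30 interferon response genes tested, 29 rose and none fell. Their median difference was 4.52 on the log2 scale (4.36 with control groups under the filter set to its level), and adjusted over the list alone all 30 rose. Besides those named above, Psmb8, a subunit of the immunoproteasome, rose by 5.12 (SE 0.106), the peptide transporter Tap1 by 4.79 (SE 0.096) and Ifit2 by 5.45 (SE 0.181), each with a limma adjusted p of at most 7.42e-07. The member that did not pass over all genes was the transcription factor Stat2, at a difference of 2.94 (adjusted p = 0.0738). The list was higher than the other genes in camera (adjusted p = 1.89e-85), and it was the only one of the 25 lists to pass when the correlation between its genes was estimated (adjusted p = 0.0151 with an estimated correlation). On every mutant array the mean of the list exceeded that of every control array (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow, and 0.119 after adjustment over the 25 lists). On the 5 arrays with Y-linked transcripts alone, a subset chosen after seeing the data, its median difference was 4.19.

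Microglia and macrophage markers were higher on the same arrays: 15 of the 20 tested rose, none fell, and the median difference was 1.78. Adjusted over the list alone, 19 rose. Aif1, a calcium-binding protein of microglia, rose by 3.31 (SE 0.403, adjusted p = 0.00198), the complement component C1qa by 2.38 (SE 0.240), Ctss by 2.26 (SE 0.219) and the Fc receptor chain Fcer1g by 2.18 (SE 0.230). The 5 members that did not pass, named here because they were so few, were P2ry12 (2.04), Cd163 (0.93), Mrc1 (0.68), Laptm5 (0.34) and Csf3r (0.13). The camera test gave an adjusted p of 7.46e-27, which did not hold with an estimated correlation (adjusted p = 0.168 with an estimated correlation). The list means of the groups did not overlap (exact permutation p = 0.0286, adjusted p = 0.119).

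Of the 21 chemokine, cytokine and innate immune genes tested, 4 rose and none fell, against 5 higher and 1 lower adjusted over the list alone. Those that rose were the monocyte-attracting chemokines Ccl12 (3.77, SE 0.385), Ccl2 (2.19, SE 0.307) and Ccl7 (1.53, SE 0.262), and Serping1, the inhibitor of complement C1 (2.88, SE 0.191). The other members kept the median of the list at 0.07. The camera test passed (adjusted p = 0.00177), the call was lost with an estimated correlation (adjusted p = 0.429 with an estimated correlation), and the list means did not overlap between the groups (exact permutation p = 0.0286, adjusted p = 0.119).

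Blood-brain barrier genes were lower in the mutants: 7 of the 23 tested fell and none rose, with 15 lower when adjusted over the list alone, and 22 of the 23 had a negative difference. The proteoglycan Spock2 fell by 0.62 (SE 0.109), Slc7a1 by 0.59 (SE 0.094), the Wnt-responsive transcription factor Lef1 by 0.53 (SE 0.080) and the iron exporter Slc40a1 by 0.52 (SE 0.099), with limma adjusted p from 0.0072 to 0.0236. With the mean of the probe sets of each gene all 4 lost the call, at differences of -0.45, -0.34, -0.54 and -0.51 and limma adjusted p of 0.251, 0.0966, 0.255 and 0.0826. For Slc7a1 that mean takes in a probe set near the floor. The next brightest probe sets of the 4 genes differed in the same direction, by -0.276, -0.425, -0.547 and -0.507, and did not pass (limma adjusted p over all probe sets from 0.263 to 0.708). The median of the list was -0.34, against -0.11 for all tested genes. The camera test passed (adjusted p = 2.26e-07), not so with an estimated correlation (adjusted p = 0.168 with an estimated correlation), and the list means of the groups did not overlap (exact permutation p = 0.0286, adjusted p = 0.119). Of 24 endothelial markers, the transcription factors Erg (-0.63, SE 0.091, adjusted p = 0.00561) and Sox17 (-0.48, SE 0.088, adjusted p = 0.0194) fell and none rose, against 3 lower adjusted over the list alone. As in the barrier list, nearly all had a negative difference, 22 of the 24. The median of the endothelial list was -0.19, its camera adjusted p was 0.042, and the call was lost both with an estimated correlation (adjusted p = 0.677 with an estimated correlation) and with each array centred on its median (adjusted p = 0.0777), 2 of the 10 of 20 settings in which it did not pass. The mean of that list was -0.42 on mutant array 4 against 0.06, -0.03 and -0.01 on the other mutant arrays. Without mutant array 4 its camera adjusted p was 0.617. Among 18 genes of endothelial activation and sprouting, the collagen chain Col15a1 (-0.65) and the lymphatic growth factor receptor Flt4 (-0.47, and -0.26 with the mean of its probe sets, limma adjusted p = 0.0884) fell and none rose, against 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.139). The other probe set of Flt4 lay under the filter on every array.

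The pericyte and mural cell list mixed directions. Of its 23 tested genes, Art3, an ADP-ribosyltransferase (1.81, SE 0.194, adjusted p = 0.000902), and Higd1b, a pericyte marker (0.85, SE 0.186, adjusted p = 0.041), rose while Pdgfrb fell on its brighter probe set, against 4 higher and 2 lower adjusted over the list alone. Its median was 0.18, its camera adjusted p was 0.00177 in the upward direction, and the call was lost with an estimated correlation (adjusted p = 0.62 with an estimated correlation). No smooth muscle contractile gene of the 16 tested passed, adjusted over the list alone or over all genes (camera adjusted p = 0.378). Acta2, smooth muscle actin, read 12.11 ± 0.25 in mutants and 12.60 ± 0.66 in controls (SD, n = 4 each), and Cald1 12.79 ± 0.29 and 12.99 ± 0.07. Among 12 adipogenic and mesenchymal progenitor genes, Dlk1, a marker of preadipocytes, rose by 1.51 (SE 0.207, adjusted p = 0.00417) and none fell, against 4 higher and 1 lower adjusted over the list alone. That list passed in camera (adjusted p = 0.00131) but not with an estimated correlation (adjusted p = 0.168 with an estimated correlation), and its exact permutation p was 0.0571.

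Few matrix genes passed. Of 29 interstitial collagen and matrix genes only Col14a1 fell, and of 17 fibroblast and meningeal markers only the transcription factor Twist1 rose (0.46, SE 0.085), with the same counts adjusted over each list alone. The camera adjusted p was 0.279 for each. None of 17 basement membrane genes passed, in either adjustment (camera adjusted p = 0.393), and Col4a1 read 14.57 ± 0.14 in mutants against 14.55 ± 0.10 in controls and Sparc 14.63 ± 0.24 against 14.51 ± 0.13 (SD, n = 4 each). In these 3 lists, and in the receptor tyrosine kinase, cell cycle and erythroid lists described next, camera pointed upwards while the mean of the list was negative; camera sets a list against the other genes, whose median was itself negative.

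Markers of other brain cells that bead isolation can carry along did not pass as single genes. None of 17 neuron markers, 15 astrocyte and radial glia markers, 8 oligodendrocyte lineage markers, 11 choroid plexus and ependymal markers or 4 erythroid genes passed, also adjusted over each list alone. Map2, a neuronal cytoskeletal gene, read 10.15 ± 0.58 in mutants against 10.02 ± 0.36 in controls, the radial glia gene Fabp7 14.65 ± 0.45 against 14.52 ± 0.20, and the choroid plexus gene Ttr 16.39 ± 0.07 against 16.36 ± 0.14 (SD, n = 4 each). The neuron list (median 0.17, camera adjusted p = 0.022) and the astrocyte list (median 0.13, camera adjusted p = 0.0238) passed upwards, and both calls were lost (adjusted p = 0.677 with an estimated correlation for each). The oligodendrocyte (camera adjusted p = 0.103), choroid plexus (0.638) and erythroid (0.777) lists did not pass.

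Few genes passed in the pathway lists closer to the receptor. Of 17 receptor tyrosine kinase and ERK feedback genes, Plat, tissue plasminogen activator, rose by 0.54 (SE 0.101, adjusted p = 0.0205) on its brighter probe set and the dimmer one differed by -0.26 (0.14 with their mean, limma adjusted p = 0.513), against 2 genes higher and 1 lower adjusted over the list alone (camera adjusted p = 0.193). Of 18 TGF-beta and BMP genes, only the latent TGF-beta binding protein Ltbp1 rose (1.01, SE 0.185, adjusted p = 0.0197), also adjusted over the list alone (camera adjusted p = 0.526). None of 14 Notch pathway genes passed in either adjustment, although 13 had a negative difference (camera adjusted p = 0.193) and the list means of the groups did not overlap (exact permutation p = 0.0286, adjusted p = 0.119). None of 26 cell cycle genes passed in either adjustment (camera adjusted p = 0.279). None of 17 hypoxia and glycolysis genes passed in either adjustment, although the list did in camera (adjusted p = 0.0379, and adjusted p = 0.434 with an estimated correlation). Of 22 immediate early genes, which respond within minutes to stimulation and to tissue dissociation, none passed over all genes and 6 were lower adjusted over the list alone. Fos read 14.31 ± 0.12 in mutants against 14.59 ± 0.13 in controls (SD, n = 4 each). That list had a median of -0.30, passed downwards in camera (adjusted p = 0.00806), lost the call with an estimated correlation (adjusted p = 0.62 with an estimated correlation) and had non-overlapping list means (exact permutation p = 0.0286, adjusted p = 0.119). Of 15 genes near Pdgfrb on chromosome 18, Csf1r, the growth factor receptor of microglia (1.06, SE 0.146), and Cd74, the invariant chain of MHC class II (1.14, SE 0.232), rose and none fell, also adjusted over the list alone (camera adjusted p = 0.279, upwards, with a list median of -0.10 and a list mean of 0.05).

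**Figure D3:**
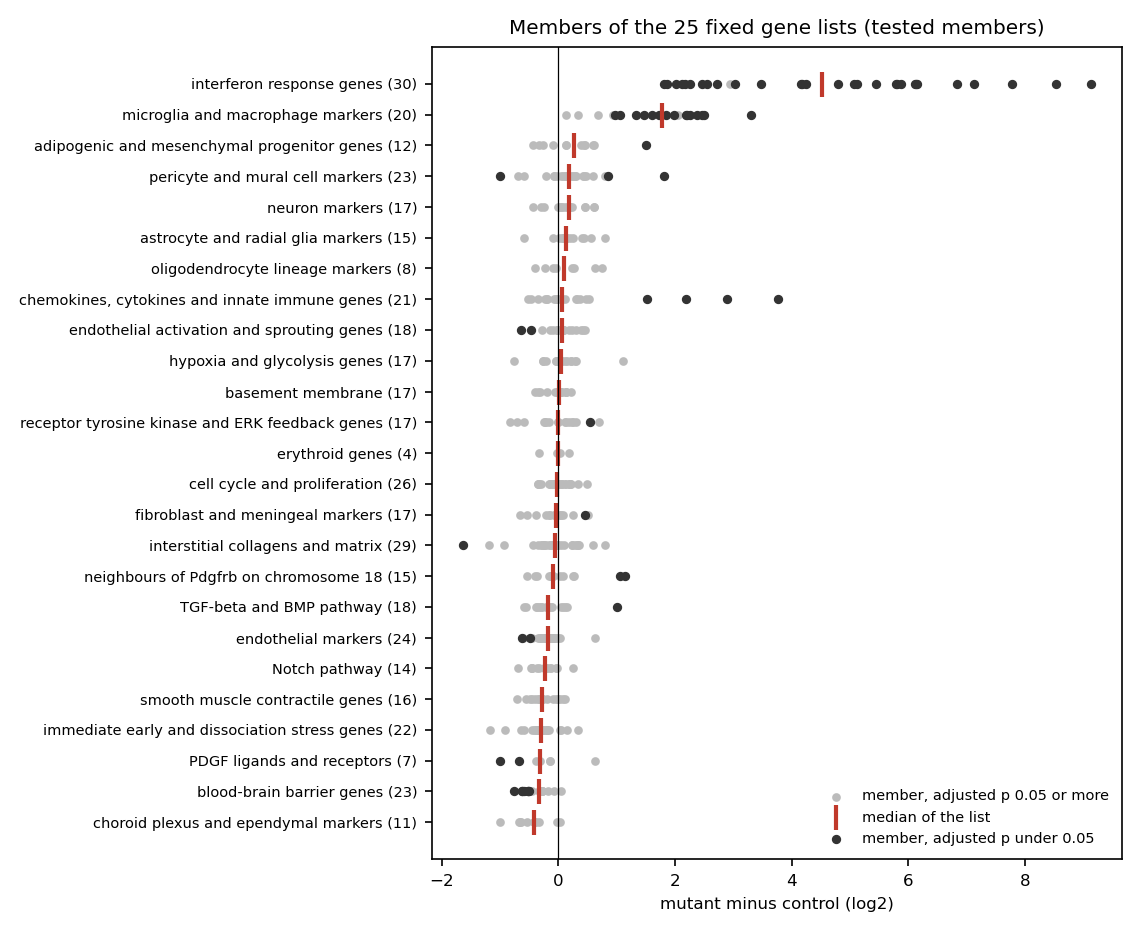
Difference between mutant and control (log2) of each tested member of the 25 fixed gene lists, 1 row per list with the number of tested members in brackets, black points for members with an adjusted p under 0.05, grey points for the others and a red bar at the median of the list. The interferon response list (median 4.52) and the microglia and macrophage list (1.78) stand to the right of 0 and the other medians lie between -0.42 and 0.27.

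In all, 11 of the 25 lists passed in camera with a preset correlation of 0.01, 8 upwards and 3 downwards, and 1 passed with an estimated correlation. The number of changed genes was 264 without mutant replicate 3 (189 higher, 75 lower), 306 without control replicate 4 (241 higher, 65 lower) and 323 without control replicate 3 (234 higher, 89 lower). In these settings the falls lost a larger part of their calls than the rises. Of the 49 named genes that passed, 17 lost the call when 1 array was left out, with limma adjusted p up to 0.149: Prxl2c, Fendrr, Tnfrsf25, Higd1b, Flt4, Pdgfa, Cd74, Sox17, Plat, Slc40a1, Col15a1, Ltbp1, Atp10d, Twist1, Col14a1, Ccl7 and Nfatc2. Y-linked transcripts were found on 3 of the 4 mutant arrays and on 2 of the 4 control arrays. RNA integrity, read as the 3' minus 5' signal of the Actb control probe sets, was 1.03 ± 0.03 in mutants and 0.99 ± 0.04 in controls (SD, n = 4 each, exact permutation p = 0.143).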

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

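Of the tests in this part, those of T, NK and neutrophil markers and the counts over other splits of the arrays were planned before their results were seen. The list means with each array centred were also chosen beforehand, but their use as a test for the barrier genes, like the other tests, was chosen afterwards. Among the 35 splits of the 8 arrays into groups of 4, only the real one called as many as 524 genes, and the highest other split called 80. The share of 1 in 35 is the smallest that these splits allow. Every other split mixes mutant and control arrays, so large differences between the genotypes widen its groups and lower its count. Chance cannot be excluded for the number of lists that passed in camera with a preset correlation: 11 of the 35 splits gave 11 lists or more, and the highest other split gave 15.

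The interferon response genes rose in the mutants by a median of 4.52 on the log2 scale, and the tables argue against a larger share of microglia and macrophages as the whole cause, since that median exceeded the one of the macrophage markers by 2.74, more than the spread of either list between arrays (at most 0.388). Unequal numbers of male and female pups do not account for it either: among the arrays with Y-linked transcripts the median rise was 4.19. Whether interferon was made in the preparation cannot be told, because 0 of the 8 interferon genes named on the array rose above the filter on the mutant arrays, and ligand made elsewhere or below the array's floor stays open. The genotype stays open as a hypothesis that no test here separates from a batch, since batches are not given in the sources used here.

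Microglia and macrophage markers rose by a median of 1.78. Whether all brain macrophage types grew equally in share cannot be told from these markers. The 15 markers taken as parenchymal rose by 0.98 more than the 4 taken as perivascular (exact permutation p = 0.0286). All of these markers are in the fixed list, which mixes microglia with other macrophages. The 15 are therefore not particular to parenchymal microglia, and the contrast does not show which type rose. The markers were divided after the values of that list were seen, so the p does not allow for that choice. T, NK or neutrophil cells carried along stay open: 0 of their 3 tested markers, all of neutrophils, passed, but Gzma, a granule protease of cytotoxic lymphocytes that the filter left out because of mutant array 4 (2.58), read 8.92, 8.0 and 8.07 on the other mutant arrays and at most 2.53 on the control arrays, and Gzmb read 4.82 on mutant array 1 and at most 2.20 on the control arrays. A larger share of microglia and a higher level of these transcripts per microglial cell both stay open, and the anti-PECAM isolation does not separate them.

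Blood-brain barrier genes were lower by a median of -0.34. An equal shift of all genes left by the normalization is argued against: with each array centred on its median the list mean still differed by -0.31, without overlap of the groups (exact permutation p = 0.0286). Centring removes only such an equal shift, and a shift that depends on brightness was not tested. A lower share of endothelial cells cannot be told apart from a fall within them, since the barrier list minus the endothelial list differed by -0.20 between the groups (exact permutation p = 0.0571), which overlapped in that measure. The overlap came from mutant array 4 (0.06), since mutant arrays 1, 2 and 3 read -0.19, -0.17 and -0.09 and the control arrays 0.03 to 0.13.

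Single arrays that stood apart from the other 3 of their group were looked for in 200 groups of values. By chance 10 would be expected and 15 were found. The groups are not independent: the sex-linked genes of mutant array 2 were counted singly, as were Clic6 and the choroid plexus list on mutant array 1. The 2 numbers therefore do not show an excess. Among immune genes, Cxcl11 read 3.83 on control array 2 against a mean of 4.09 on the others, and Tap1 5.73 there against 5.43. Atp10d read 8.13 on mutant array 3 against 6.49. Clic6, a choroid plexus gene, read 8.88 on mutant array 1 against 10.63 and 9.56 on control array 2 against 11.30, and the mean of the choroid plexus list on mutant array 1 was -1.23 against 0.11. Cald1 read 12.88 on control array 1 against 13.02, Hbb-b2 7.40 on control array 3 against 7.49 and Aldoa 12.27 on mutant array 2 against 12.20. The mean of the adipogenic list was -0.11 on mutant array 1 against 0.21, and 0.05 on control array 4 against -0.19. On mutant array 2, Xist read 13.01 against 2.19 and the Y-linked Eif2s3y 2.30 against 10.37, Kdm5d 2.18 against 7.26 and Uty 2.18 against 6.53, the pattern of a female pup among male ones. Outside the named genes, 39 probe sets without a single gene symbol passed and were higher on every mutant array than on every control array, by up to 8.16. A further 11 such probe sets passed and were lower in the mutants.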

How the results depend on the processing

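Of 24 alternatives, 8 of which left out an array, the one with only the 5 arrays that showed Y-linked transcripts was chosen after seeing the data; the cause of the shifts below was not tested unless given. The 524 changed genes became 241 with a fold of at least 2 and 246 with an adjusted p under 0.01, by construction; 82 (81 higher, 1 lower) on the 5 arrays with Y-linked transcripts, where fewer samples were used; and 3158 (895 higher, 2263 lower) with array weights, which ran from 0.357 for mutant array 1 to 6.60 for mutant array 3. Left-out arrays gave 264 (without mutant replicate 3) to 539 (without mutant replicate 4), with 306 without control replicate 4 and 323 without control replicate 3. The remaining alternatives that refitted the genes gave 373 to 582 genes, and testing every probe set singly gave 586 probe sets. With the replicate number as a block, 259 genes changed (221 higher, 38 lower). Whether same-numbered brains share a litter or day is not given in the sources used here. The deviations of same-numbered arrays correlated at -0.084, -0.479, -0.201 and 0.303. Each mutant array correlated best with a control array of another number, which does not exclude a shared litter or day. Of the 11 lists past the threshold, 1 passed with an estimated correlation and 6 passed in fry, in which the PDGF list passed as well, 7 in all; left-out arrays gave 8 (without mutant replicate 4) to 14 (without mutant replicate 1). Without mutant replicate 4 the endothelial (adjusted p = 0.617), neuron (0.211), astrocyte (0.201) and hypoxia (0.0889) lists lost the call, as they did without control replicate 2 (0.157, 0.506, 0.157 and 0.0573); without control replicate 1 the endothelial (0.0767), astrocyte (0.0691) and hypoxia (0.092) lists did, and without mutant replicate 2 the astrocyte list (0.12). The endothelial list also missed the threshold with the stricter filter (0.0666), the mean of probe sets (0.0935), the preference among probe sets (0.0625), array weights (0.343) and fry (0.132). Lists that did not pass with all arrays passed without mutant replicate 1 (oligodendrocyte 0.000411, interstitial collagen 0.0165 and fibroblast 0.0249), without mutant replicate 4 (endothelial activation 0.00859), without control replicate 1 (smooth muscle 0.0177) and without control replicate 2 (choroid plexus 0.0277). The interferon response list passed in all 20 settings in which lists were tested. Lists with an exact permutation p under 0.05 numbered 6, and 4 (without control replicate 3) to 7 (without mutant replicate 1) with an array left out. With an array left out the assignments are fewer, and a list whose groups do not overlap can still miss that threshold. Pdgfrb ran from -1.08 to -0.91 with an array left out; it was -0.46 (limma adjusted p = 0.144) with the mean of its probe sets, -1.09 (adjusted p = 0.0739) on the 5 arrays with Y-linked transcripts, and 0.087 (adjusted p = 0.876), reversed, where the other probe set was preferred, a result of the probe sets themselves. Of the 49 named genes that passed, 15 passed in every setting, 17 lost the call when at least 1 array was left out and Pdgfrb alone changed sign. Calls were lost by 32 on the 5 arrays with Y-linked transcripts, by 18 with the replicate number as a block, by 15 without the filter, by 7 with each array centred (Spock2, Slc40a1, Sox17, Col15a1, Flt4, Pdgfa and Tnfrsf25) and by 7 with the mean of probe sets (Pdgfrb, Lef1, Slc7a1, Spock2, Slc40a1, Flt4 and Plat). The permutation of list means was not run with the replicate block, where swaps within pairs cannot give a p under 0.05. Signal over background limits the genes left out as dim, 6748 of them, whose changes are not resolved here.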

Other observations

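The lists, genes and tests in this part were chosen after seeing the data, except the test of the genes around Pdgfrb, which was planned before its result was seen. All 12 tested genes of MHC class I and peptide loading rose, with a median of 2.63 on the log2 scale, from Nlrc5, the transcriptional activator of class I genes (5.39, SE 0.208), to the trimming peptidase Erap1 (1.08, SE 0.15); Tap1, H2-K1, H2-D1 and B2m of these are also in the interferon response list. All 4 tested MHC class II genes rose, among them H2-Aa (3.89, SE 0.232) and H2-Ab1 (2.63, SE 0.193), while Ciita, their master regulator, lay below the filter. The 4 tested immunoproteasome genes rose by a median of 3.96, Psmb10 by 2.86 and Psme1 by 1.20, whereas none of 14 subunits of the constitutive proteasome passed (median 0.10, camera adjusted p = 0.00166, and adjusted p = 0.373 with an estimated correlation). All 10 tested guanylate-binding and immunity-related GTPases rose, by a median of 4.21, with Gbp8 at 5.95 and Gbp6 at 5.69. These are fitted differences: Nlrc5, H2-Aa and Gbp8, and Dhx58, Ifi204, C1ra, Cfb and BC023105 among those given next, lay under the filter on all control arrays.

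Of 10 tested sensors of foreign or misplaced nucleic acid, 7 rose, among them Dhx58 (5.54), Ifi204 (6.02) and Ifih1 (3.36), and Sting1 (1.38, adjusted p = 0.0976), Cgas (0.70, adjusted p = 0.205) and Mavs (-0.17, adjusted p = 0.514) did not pass. Of 9 complement genes 7 rose: C2 by 6.19, C1ra by 3.66, Cfb by 3.17, Serping1 by 2.88 and the 3 chains of C1q, while C1s1 (0.47) and Cfi (0.14) did not pass. None of the 4 interferon receptor genes passed over all genes. The 8 interferon genes named on the array did not exceed 2.84 on any array.

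A candidate explanation for part of the falls is lower Wnt signalling in the vessels, offered as a hypothesis. Of 13 tested Wnt and beta-catenin target genes 6 fell and none rose: Notum (-0.82), Dkk2 (-0.77), Nkd1 (-0.76), Ppard (-0.64), Lef1 (-0.53) and Sox17 (-0.48). The list mean was lower by 0.52 (difference -0.52, exact permutation p = 0.0286, 0.0381 after adjustment over 12 lists chosen after seeing the data; lower on 4 of 4 mutant arrays than on every control array), and the list passed in camera (adjusted p = 4.93e-06, and adjusted p = 0.0335 with an estimated correlation). Most of those 12 lists hold immune genes and passed as well, so adjustment over them is lenient and does not allow for their choice. Over the 25 fixed lists, the same exact permutation p of 0.0286 became 0.119. For the 9 targets that are in neither the barrier nor the endothelial list the difference was -0.58 (exact permutation p = 0.0286), with a camera p of 0.000262 and a p of 0.0574 with an estimated correlation. Axin2, a widely used target, did not pass (-0.39, adjusted p = 0.189), and the test cannot tell lower signalling from fewer endothelial cells.

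A stretch of chromosome 18 carried along with the knock-in allele might alter genes around Pdgfrb. Of the 50 tested genes on either side, 6 of 100 (6%) changed against 4.56% elsewhere, an odds ratio of 1.34 (95% interval 0.476 to 3.04, Fisher's exact test, two-sided, p = 0.465), which leaves the question open. The 6 were Iigp1 (7.78), Gm4951 (6.28), BC023105 (4.17), Cd74 (1.14), Csf1r (1.06) and Ldlrad4 (-0.84). Of these, Iigp1 is also in the interferon response list and Csf1r in the microglia and macrophage list, and both lists rose as a whole.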
